A study of Mus musculus with 4 samples.

How the data were processed

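RNA-seq was made from lineage-negative cells sorted from mouse bone marrow. The labels also call these cells hematopoietic stem and progenitor cells, or stem cells. The groups were wild type and a conditional knockout of Mel18 in the blood system. Mel18 is encoded by Pcgf2, a subunit of Polycomb repressive complex PRC1. There were 4 libraries, 2 per group, each from a separate mouse per the labels. cDNA was made with a low-input SMART-Seq kit and libraries with Nextera XT, per the labels' protocols, and this chemistry does not mark strand.

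Reads were handled with FastQC, MultiQC 0.11.5, Trimmomatic 0.40, STAR 2.5 and edgeR 3.28.1 on build mm10, per the submitters' processing notes. The read counter, the annotation release and the strand setting are not given in the sources used here. The deposited gene table holds whole-number counts per gene for 15607 genes, not normalized. It holds log2 CPM and log2 RPKM values per library, also deposited by the authors. The RPKM column was tested on the table and equals the log2 CPM less the log2 of gene length in kb to within 9.48e-14 in every row. The deposited p-value, false discovery rate and log2 fold change come from the authors' own comparison of knockout with wild type, per the file headers. Each row of the table has at least 24 counts in all, and at least 10 in 1 library. A further 2 columns of per-sample values belong to no sample described in the labels and were not used. Of the 15607 gene identifiers, 15135 matched GENCODE M21 on mm10 with version number, and all 15135 had the same chromosome, start and end there.

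Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. TMM scaling, robust quasi-likelihood fits and quasi-likelihood F tests were used, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The filterByExpr step of edgeR removed 0 genes, so the low-count filter was that already in the table. A second count required at least a 2-fold change beside the adjusted p. Standard errors of log2 fold changes were taken from the F statistic. CPM values used TMM-scaled library sizes, and group values are the mean ± SD of 2 mice. The model left 2 residual degrees of freedom per gene, and the common biological coefficient of variation was 13.3%.

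The 30 gene lists were fixed before the data were examined, as were the tests, the alternatives other than those named as added, and the rule for named genes. Of the 1089 symbols listed, 919 were in the table, and 31 stood in more than 1 list. Lists with at least 5 measured members, 28 in number, were tested with camera of limma 3.58.1 (two-sided, preset correlation 0.01), with adjustment over the lists. Camera compares the list with all other genes, while fry, an alternative, asks whether the list's genes move one way on balance. The rule named Pcgf2 and Bmi1, then genes past the threshold with a mean of at least 2 CPM whose 2 knockout libraries lay on the same side of both wild type libraries, up to 12 with the largest rise and up to 12 with the largest fall. Predicted genes with Gm or Rik symbols were left out of that rule. Where fewer than 5 genes passed in a direction, the 8 with the smallest p under the other criteria were taken. From each list discussed, up to 4 members with the smallest p were eligible, as was any Polycomb, Hox or cyclin-dependent kinase inhibitor gene past the threshold. Genes named outside the rule are said to be so, and 2 genes that the rule allowed are not reported here.

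The procedure was tested on counts simulated for all 15607 genes from the real means, library sizes and gene-wise dispersions, with 200 genes changed in each of 3 runs. The changed genes were drawn from those with a mean of at least 2 CPM, so recovery at lower levels was not tested. The quasi-likelihood test recovered 48.8% of the genes changed 1.5-fold, 78.1% of those changed 2-fold and 98.0% of those changed 4-fold. Of its calls 13.5% were false, or 23.3 false calls per run. A second simulation with dispersions taken from the trend was added after this result. There 3.96% of the quasi-likelihood calls were false, or 6.33 per run. These shares depend on the 200 genes changed, so they do not carry over to the genes called in the real data. A list of genes raised 1.5-fold in a further simulation was called, and 0 of the other 27 lists were. Genes were drawn independently there, so lists whose members move together were not simulated. The absence of other calls therefore does not test the preset correlation of camera.

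Alternatives were edgeR with DESeq2 size factors, total counts only, the DESeq2 1.42.0 Wald test, limma voom, quasi-likelihood fits without robust estimation, the edgeR likelihood ratio test, no filter, a filter of 1 CPM in 2 libraries, removal of mitochondrial, hemoglobin, X inactivation and Y-linked genes, and removal of each library in turn. For the lists, camera with an estimated correlation, camera on ranks and fry were run. With an estimated correlation camera also judges each list on the 2 residual degrees of freedom of the model. A call can therefore be lost without any correlation between members. Pseudocount settings planned for normalized values did not apply, since counts were given. Added after seeing the data were a replacement count for Hoxb4 in knockout mouse 5 and the removal of 5 genes high in 1 library. The transcripts nearest to a pair of pseudogenes were found with blastn 2.17.0+ among GENCODE M21 transcripts. Genes with near-identical copies, such as Ig variable segments, processed pseudogenes and their parent genes, Gapdh and ribosomal protein genes, may have lost or gained reads in counting, and their values are uncertain. Intervals and floors below cover counting error only, because the reads carried no molecular identifiers.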

Results

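The transcriptome of lineage-negative bone marrow cells, a fraction depleted of mature blood cells and enriched for stem and progenitor cells, was measured in 4 mice. Mice 1 and 3 were wild type, and mice 5 and 6 carried the conditional Mel18 knockout. Total counts were 35599564 and 37197363 in wild type mice 1 and 3, and 46240864 and 44642002 in knockout mice 5 and 6. Each library had counts for 15603 or more of the 15607 genes. Across genes, which are not independent replicates, Pearson's r of log2 CPM between libraries ranged from 0.987 (wild type mouse 1 and knockout mouse 5) to 0.993 (knockout mice 5 and 6). Wild type mouse 3 had a higher r with knockout mice 5 and 6 (0.990 and 0.991) than with wild type mouse 1 (0.989).

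The study asked whether loss of Mel18 alters transcription in these cells, so its own transcript was examined first. Pcgf2, the gene of Mel18, was not lower in the libraries labelled knockout. It had 210 and 158 counts in wild type mice 1 and 3, and 303 and 321 in knockout mice 5 and 6. The level was 5.05 ± 0.974 CPM in wild type and 6.87 ± 0.446 CPM in knockout (SD, n = 2), a log2 fold change of 0.44 ± 0.20 (SE) that did not pass the edgeR quasi-likelihood test (adjusted p = 0.575). The authors' deposited table gives Pcgf2 a log2 fold change of 0.44 and an adjusted p of 0.846. The counts cover the whole gene (mm10, chromosome 11, 97688823 to 97700497, minus strand). The exons removed by the conditional allele are not stated in the labels, so reads from remaining exons may be included and this count neither checks nor contradicts the genotype. All directions below are therefore between libraries labelled knockout and libraries labelled wild type. Bmi1, the closest homologue of Mel18 within PRC1, was at 34.8 ± 3.93 CPM in wild type and 36.4 ± 2.92 CPM in knockout (SD, n = 2), with a log2 fold change of 0.064 ± 0.11 (SE) and a quasi-likelihood adjusted p of 0.870.

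In libraries labelled knockout, transcripts of the platelet chemokines Ppbp and Pf4 and of Timp3 rose, while Trib1, Osm, Nr4a1, Dusp1, Fpr2 and Cd33 were among the genes that fell. Of 15607 genes, 21 passed the edgeR quasi-likelihood test, 5 higher and 16 lower. At least 2-fold changes were seen in 8 of them, 4 higher and 4 lower. Ppbp (chromosome 5, 90768518 to 90770063) went from 10.4 ± 0.832 to 32.0 ± 3.25 CPM (SD, n = 2), with a log2 fold change of 1.62 ± 0.12 (SE) and a quasi-likelihood adjusted p of 0.0160. Its neighbour Pf4 (chromosome 5, 90772435 to 90773383) went from 29.2 ± 0.343 to 55.1 ± 7.45 CPM (SD, n = 2), with a log2 fold change of 0.92 ± 0.11 (SE) and an adjusted p of 0.0477. Timp3, an inhibitor of matrix metalloproteinases, rose from 6.49 ± 0.512 to 17.4 ± 1.20 CPM (SD, n = 2; log2 fold change 1.42, adjusted p = 0.0318). Only these 3 genes met every criterion for a named rise. The next 5 by p did not pass the adjusted test. They were Gp1ba, a subunit of the platelet receptor for von Willebrand factor (log2 fold change 1.07, adjusted p = 0.0631), the collagen chaperone Serpinh1 (1.95, adjusted p = 0.0840), the matrix proteoglycan Bgn (1.36, adjusted p = 0.127), the Ig heavy chain segment Ighv5-4 (1.15, adjusted p = 0.132) and Mrvi1 (1.12, adjusted p = 0.132). Also past the test, and named outside the rule after their values were seen, were the processed pseudogenes Gm5823 and Gm18860, which had 5 and 7 counts in the wild type libraries together and 1281 and 535 in the knockout libraries together.

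Among the genes that fell, the largest change was in Igkv12-41, an Ig kappa variable segment whose reads can be shared with related segments (log2 fold change -1.33, quasi-likelihood adjusted p = 0.0430). Trib1, a pseudokinase that directs degradation of the transcription factor C/EBP alpha, fell from 46.8 ± 3.34 to 18.9 ± 0.976 CPM (SD, n = 2; chromosome 15, 59648350 to 59657099), with a log2 fold change of -1.31 ± 0.10 (SE) and an adjusted p of 0.0160. The cytokine gene Osm, encoding oncostatin M, fell from 77.6 ± 14.8 to 35.3 ± 0.0866 CPM (SD, n = 2; log2 fold change -1.14, adjusted p = 0.0477). Nr4a1, an orphan nuclear receptor induced by many stimuli, went from 37.1 ± 0.689 to 17.1 ± 1.18 CPM (SD, n = 2; log2 fold change -1.12, adjusted p = 0.0260). The formyl peptide receptor Fpr2 (log2 fold change -0.97, adjusted p = 0.0353), the neutrophil transcript Retnlg (-0.92, adjusted p = 0.0449) and Ifitm6 (-0.90, adjusted p = 0.0260) also fell. So did the phosphatase gene Dusp1 (log2 fold change -0.84, adjusted p = 0.0430), Btg2 (-0.74, adjusted p = 0.0477), and the myeloid surface receptors Cd300lf (-0.73, adjusted p = 0.0430) and Cd33 (-0.73, adjusted p = 0.0390). The number of genes depended strongly on the test and on which library was left out, where the spread then came from the complete pair alone. It was 289 without wild type mouse 1, 855 without wild type mouse 3, 5 without knockout mouse 5 and 17 without knockout mouse 6, and limma voom called 0 genes (1363 at an unadjusted p under 0.05, against 1388 for quasi-likelihood). Of the 21 genes, 20 were called without wild type mouse 1, 20 without wild type mouse 3, 2 without knockout mouse 5 and 6 without knockout mouse 6.

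**Figure D1:**
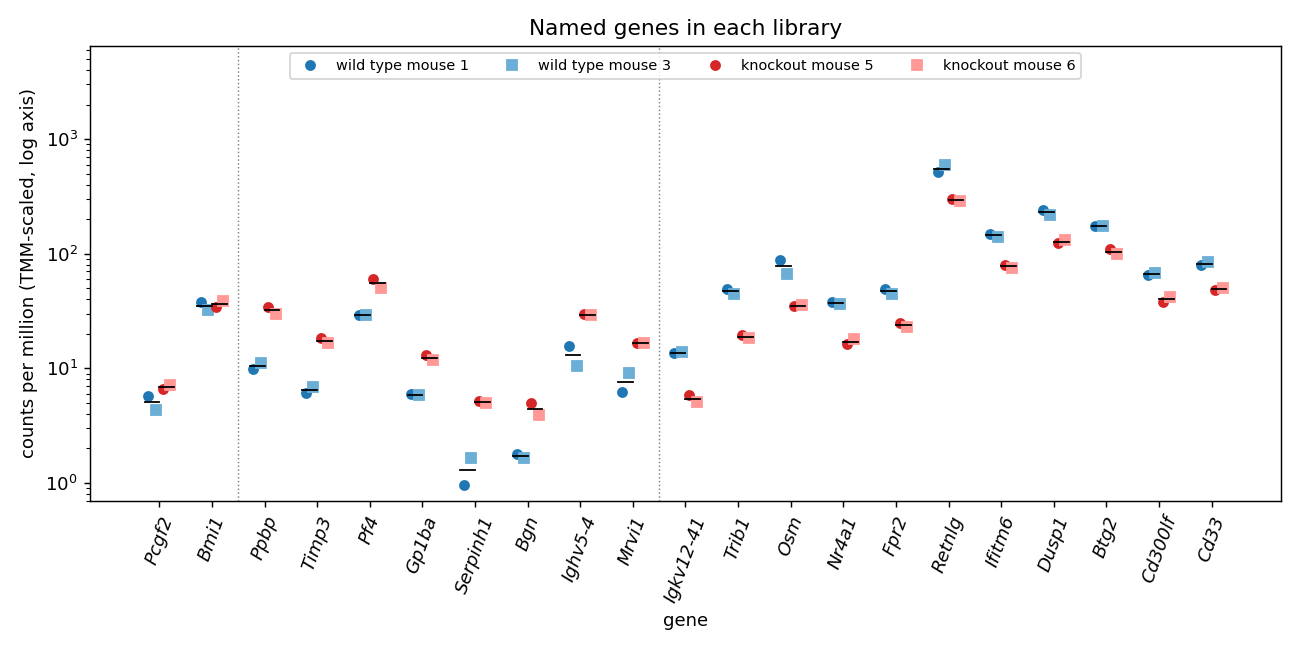
CPM on a log axis of each named gene in each library, with a black bar at the mean of each group. Dotted lines part Pcgf2 and Bmi1, the 8 genes with the smallest p among those higher in both knockout libraries with a mean of at least 2 CPM and no Gm or Rik symbol, and 11 of the largest falls past the test; Ppbp rises from 10.4 to 32.0 CPM and Trib1 falls from 46.8 to 18.9 CPM.

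The authors' deposited table holds 176 genes at an adjusted p under 0.05, 57 higher and 119 lower in knockout, and includes all 21 genes called by quasi-likelihood. The edgeR likelihood ratio test on the deposited counts called 177 genes, 57 higher and 120 lower, of which 176 were those of the authors' deposited table. The likelihood ratio test does not allow for the uncertainty of each gene's dispersion, and the quasi-likelihood test does.

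Immediate early genes, which respond within minutes to growth factor, cytokine or stress signals, were lower. Of 35 measured members, 5 fell in the test over all genes, 0 rose and 30 did not pass. Adjusted over the list alone, 23 were lower. Those with the smallest p were Nr4a1, Dusp1, Klf2 and Btg2, and Klf2, a zinc finger factor of lymphocyte quiescence, went from 123 ± 0.352 to 77.9 ± 0.321 CPM (SD, n = 2; log2 fold change -0.66, quasi-likelihood adjusted p = 0.0430). The median log2 fold change of the list was -0.45 (camera adjusted p = 1.03e-15; adjusted p = 0.251 with an estimated correlation), and fry gave an adjusted p of 0.00014. Both knockout libraries lay below both wild type libraries for 26 of the 35 genes, and for 20.9% of all genes, where chance gives 16.7%.

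NF-kB and cytokine genes were lower as a list of 34, with a median log2 fold change of -0.32 (camera adjusted p = 1.19e-08; adjusted p = 0.251 with an estimated correlation). None passed over all genes by quasi-likelihood (0 of 34, with 16 at an unadjusted p under 0.05), and the authors' deposited table calls 6 of them, all lower. Adjusted over the list alone, 14 were lower. Nfkbiz (log2 fold change -0.91), Nfkbia (-0.48), Tnf (-0.85) and Il1b (-0.69) had the smallest p, with quasi-likelihood adjusted p over all genes of 0.0846, 0.0846, 0.102 and 0.117. Nfkbia also stands in the immediate early list and Il1b in the neutrophil list. In the same libraries the median log2 fold changes of neutrophil and of monocyte, macrophage and dendritic cell genes were -0.63 and -0.19, as they were beside the immediate early and interferon response genes.

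Interferon response genes were lower as a list. Of 56 measured members, 1 fell over all genes, 0 rose and 55 did not pass, and adjusted over the list alone 25 were lower. The median log2 fold change was -0.42 (camera adjusted p = 6.04e-19; adjusted p = 0.251 with an estimated correlation), and 47 of the 56 were lower in both knockout libraries than in both wild type libraries, against 20.9% of all genes. Samd9l was the called member, at 91.2 ± 1.63 CPM in wild type and 58.9 ± 2.88 CPM in knockout (SD, n = 2; log2 fold change -0.63, quasi-likelihood adjusted p = 0.0488). The antiviral gene Oasl2 (log2 fold change -0.99, adjusted p = 0.0548), the interferon regulatory factor Irf7 (-0.68, adjusted p = 0.0814) and Rtp4 (-1.05, adjusted p = 0.119) followed without passing.

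Neutrophil and granule genes were lower, by a median log2 fold change of -0.63 over 36 members (camera adjusted p = 3.94e-13; adjusted p = 0.474 with an estimated correlation). Fpr2, Retnlg and Cxcr2 fell over all genes, 0 rose and 33 did not pass, and adjusted over the list alone 21 were lower. The list did not pass fry (adjusted p = 0.178). Cxcr2, the chemokine receptor of mature neutrophils, was at 84.2 ± 4.70 CPM in wild type and 52.8 ± 0.945 CPM in knockout (SD, n = 2; log2 fold change -0.67, quasi-likelihood adjusted p = 0.0449). The collagenase gene Mmp8 had a log2 fold change of -0.80 (adjusted p = 0.0572). Named outside the rule, the abundant granule genes S100a8 and S100a9 had log2 fold changes of -0.77 and -0.77 (adjusted p = 0.281 and 0.311), whereas the primary granule genes Mpo and Elane, made early in the lineage, had 0.045 and 0.010 (adjusted p = 0.948 and 0.990). Without wild type mouse 3 the median of the list was -0.35 (camera adjusted p = 8.26e-07).

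Megakaryocyte genes were higher, with a median log2 fold change of 0.42 over 29 members (camera adjusted p = 1.21e-08; adjusted p = 0.408 with an estimated correlation). Ppbp and Pf4 rose over all genes, 0 fell and 27 did not pass. Adjusted over the list alone, 13 were higher and 3 lower. The list did not pass fry (adjusted p = 0.107). Gp1ba and the thrombin receptor gene F2rl2 (log2 fold change 0.93, quasi-likelihood adjusted p = 0.155) did not pass over all genes. In the same libraries the stroma and endothelium list had a median of 0.70.

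Bone marrow stroma and endothelium genes, some of them markers of cells outside the blood lineages, were also higher as a list in the libraries labelled knockout. The 30 measured members had a median log2 fold change of 0.70 (camera adjusted p = 1.44e-06; adjusted p = 0.354 with an estimated correlation). None passed over all genes by quasi-likelihood (0 of 30, with 12 at an unadjusted p under 0.05), and the authors' deposited table calls 6 of them, all higher. Adjusted over the list alone, 11 were higher. With a filter of 1 CPM in 2 libraries the median was 0.30 (camera adjusted p = 0.0051). Bgn had 65 and 60 counts in wild type mice 1 and 3, and 230 and 173 in knockout mice 5 and 6. Lum had 0 and 3 against 42 and 26 counts, and the count of 0 allows up to 0.0820 CPM in that library. The osteoblast genes Bglap (2 and 16 against 113 and 82 counts) and Ibsp (16 and 36 against 98 and 121) followed. Col1a1, the main collagen gene of bone, named outside the rule, was at 4.73 and 80.1 CPM in wild type mice 1 and 3, and at 352 and 326 CPM in knockout mice 5 and 6. Its log2 fold change of 3.00 ± 1.69 (SE) did not pass the test (quasi-likelihood adjusted p = 0.682), and the wild type mice lay far apart.

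**Figure D2:**
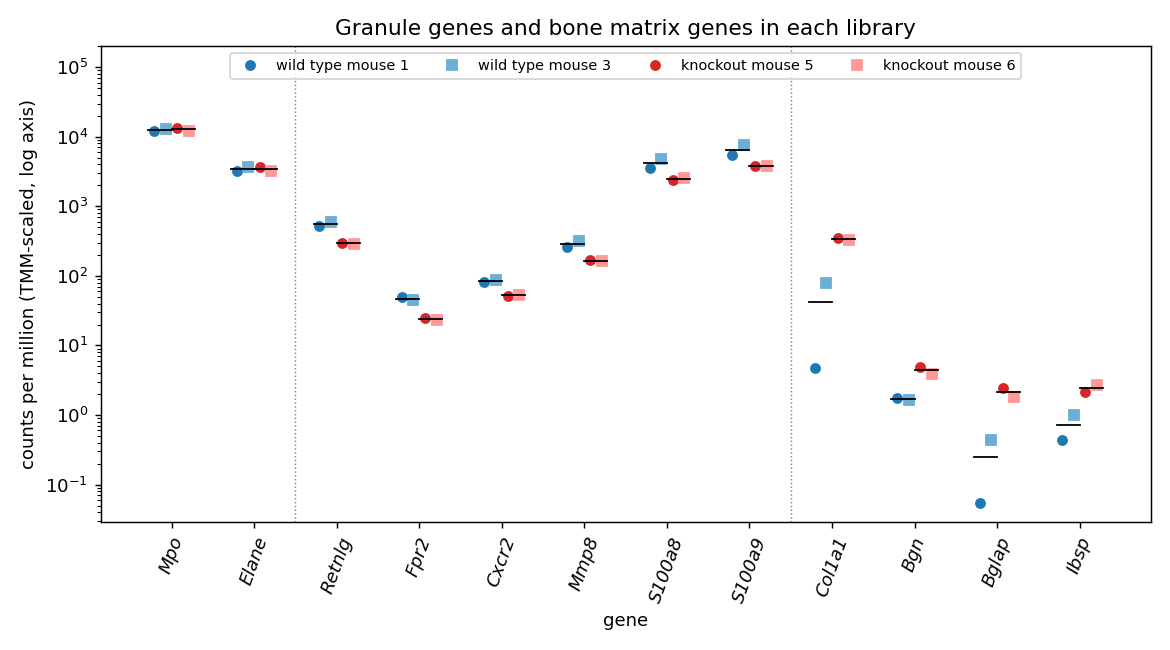
CPM on a log axis in each library, with a black bar at the mean of each group. Dotted lines part the primary granule genes Mpo and Elane, 6 later granule and neutrophil genes, and 4 bone matrix genes; Col1a1 lies at 4.73 and 80.1 CPM in the wild type libraries and at 352 and 326 CPM in the knockout libraries.

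Erythroid genes had a median log2 fold change of 0.25 over 43 members (camera adjusted p = 6.33e-06; adjusted p = 0.682 with an estimated correlation), led by the transferrin receptor Tfrc (0.35), Gfi1b (0.38) and Sphk1 (0.40). Smaller positive medians went with camera calls for S phase genes (0.091, adjusted p = 0.000686; 0.682 with an estimated correlation), the list of ribosome biogenesis and MYC-responsive genes (0.093, led by Cad, an enzyme of pyrimidine synthesis, at 0.40; camera adjusted p = 0.000567; 0.343 with an estimated correlation), G2 and M phase genes (0.065, adjusted p = 0.0318; 0.764 with an estimated correlation), heat shock and chaperone genes (0.20, adjusted p = 0.018; 0.682 with an estimated correlation) and imprinted genes (0.11, adjusted p = 0.0318; 0.408 with an estimated correlation). No member of these 6 lists passed over all genes by quasi-likelihood, and the authors' deposited table calls 1, the imprinted noncoding RNA H19 (0 and 6 counts in wild type mice 1 and 3, 27 and 22 in knockout mice 5 and 6). Without wild type mouse 1 the calls of S phase (median 0.028, adjusted p = 0.357), erythroid (0.098, adjusted p = 0.108) and heat shock genes (0.11, adjusted p = 0.637) were lost, and the median of G2 and M phase genes turned to -0.049 (adjusted p = 0.168). Without wild type mouse 3 the medians were 0.19 for S phase, 0.15 for G2 and M phase, 0.38 for erythroid and 0.29 for heat shock genes, all called. Imprinted genes had a median of 0.32 without wild type mouse 1 (adjusted p = 0.00216), 0.081 without wild type mouse 3 (adjusted p = 0.0788), 0.046 without knockout mouse 5 (adjusted p = 0.0786) and 0.12 without knockout mouse 6 (adjusted p = 0.0448). Without knockout mouse 5 the medians of G2 and M phase (0.046, adjusted p = 0.211) and erythroid genes (0.080, adjusted p = 0.270) were not called. Without knockout mouse 6 the erythroid median was 0.41 and called, while those of heat shock (0.11, adjusted p = 0.219) and ribosome biogenesis and MYC-responsive genes (0.092, adjusted p = 0.121) were not.

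Negative medians with camera calls were found for the lymphoid and B cell progenitor list (-0.25, led by Ms4a1 at -0.84; camera adjusted p = 0.000477; 0.474 with an estimated correlation), T and NK cell genes (-0.33, led by Il2ra at -0.84; camera adjusted p = 0.000567; 0.682 with an estimated correlation), monocyte, macrophage and dendritic cell genes (-0.19, led by Cd14 at -0.66; camera adjusted p = 0.00397; 0.474 with an estimated correlation) and mast cell, basophil and eosinophil genes (-0.24; adjusted p = 0.0274; 0.682 with an estimated correlation). No member of these 4 lists passed over all genes by quasi-likelihood (adjusted p = 0.294 for Ms4a1, 0.260 for Il2ra and 0.230 for Cd14). At an unadjusted p under 0.05 there were 10, 1, 3 and 3 members in that order, and the authors' deposited table calls 1, the chemokine Ccl3 of the mast cell list (log2 fold change -0.84 by quasi-likelihood, adjusted p = 0.447). The p53 target list had a median of -0.064 (camera adjusted p = 0.0318, and 0.408 with an estimated correlation). Btg2, also in the immediate early list, was lower, and Phlda3 had a log2 fold change of 0.83 (quasi-likelihood adjusted p = 0.209). Adjusted over the p53 list alone, 2 members were lower and 1 higher. The 6 measured cyclin-dependent kinase inhibitor genes had a median of -0.19 (camera adjusted p = 0.0266; 0.408 with an estimated correlation). None of them passed over all genes by quasi-likelihood (2 at an unadjusted p under 0.05), the authors' deposited table calls Cdkn2d, and adjusted over the list alone 2 were lower, Cdkn2d (log2 fold change -0.38) and Cdkn1b (-0.31). Without wild type mouse 1 the tests of T and NK cell and of mast cell genes changed direction (medians 0.048 and -0.0015, adjusted p = 0.315 and 0.829), and without wild type mouse 3 their medians were -0.61 and -0.43, both called. The p53 targets were not called in any of the 4 fits with 1 library left out (medians -0.097, -0.11, -0.052 and -0.044, adjusted p = 0.0885, 0.175, 0.0995 and 0.0651 without mice 1, 3, 5 and 6). Cyclin-dependent kinase inhibitors had a median of -0.29 without wild type mouse 3 (adjusted p = 0.175), -0.13 without knockout mouse 5 (adjusted p = 0.223) and -0.33 without knockout mouse 6 (adjusted p = 0.0323). Monocyte genes were not called without wild type mouse 3 (-0.105, adjusted p = 0.525) or knockout mouse 5 (-0.12, adjusted p = 0.123). Lymphoid genes had a median of -0.41 without knockout mouse 5 (adjusted p = 1.88e-06) and -0.15 without knockout mouse 6 (adjusted p = 0.0551), where mast cell genes had -0.20 (adjusted p = 0.310).

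**Figure D3:**
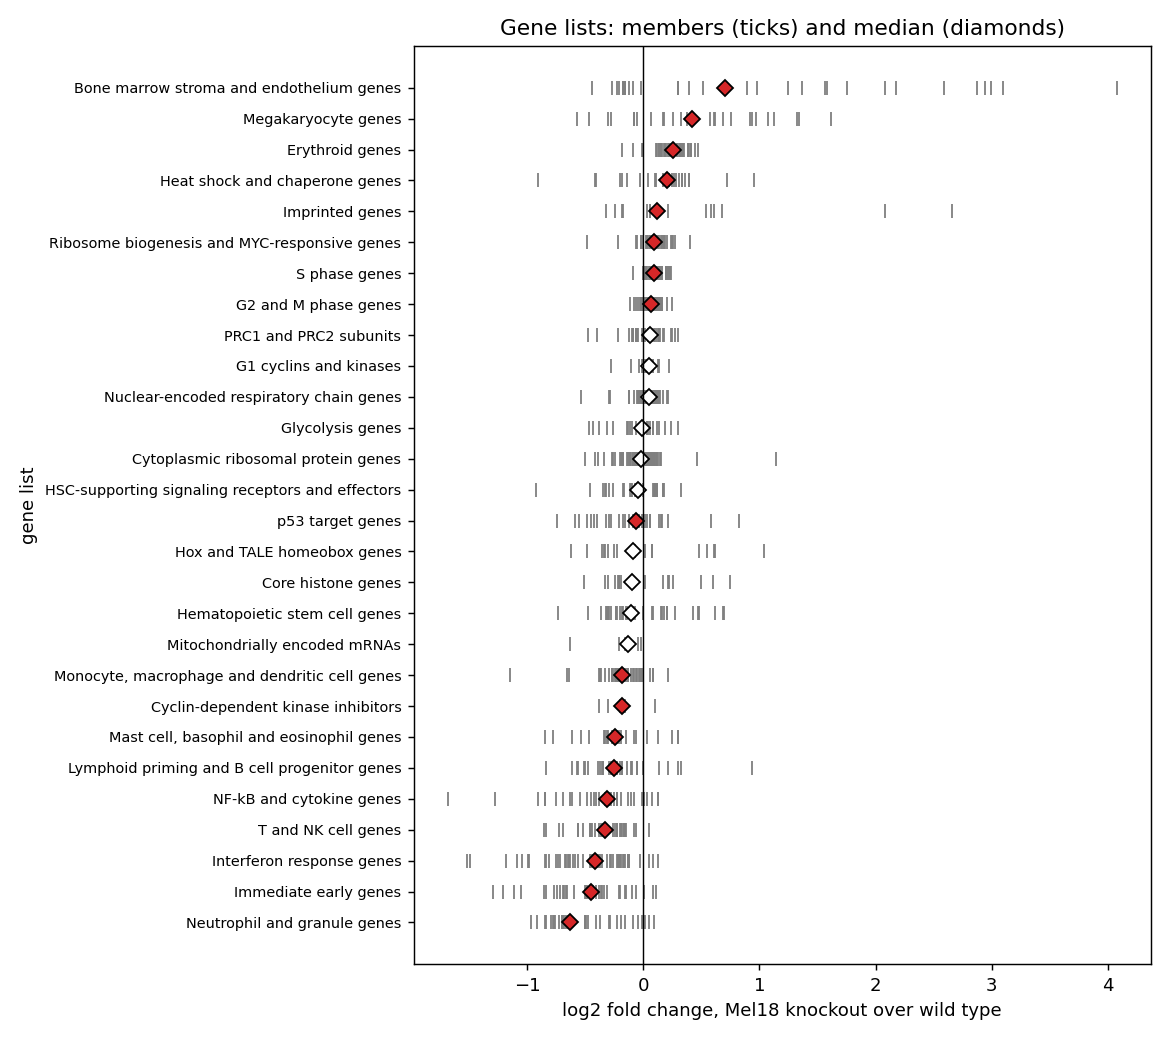
Log2 fold change of knockout over wild type for each member (ticks) of the 28 tested gene lists, with the median of each list as a diamond. Red diamonds mark lists past camera with the preset correlation, from neutrophil and granule genes at -0.63 to stroma and endothelium genes at 0.70.

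Lists tied to the function of Mel18 and to stem cell identity did not pass camera. The 35 measured PRC1 and PRC2 subunits had a median log2 fold change of 0.058 (adjusted p = 0.230), with Phf1 at -0.40 (quasi-likelihood adjusted p = 0.230) and Kdm2b at 0.25 (adjusted p = 0.482) the smallest p. The 19 measured Hox and TALE genes had a median of -0.087, a mean of 0.014 and a test direction of lower (camera adjusted p = 0.324), with Hoxb3 at -0.48. A filter of 1 CPM in 2 libraries brought that list past the threshold (median -0.23, adjusted p = 0.0159), as did leaving out wild type mouse 3 (-0.16, adjusted p = 0.0497). Without wild type mouse 1 its direction turned to higher (0.036, adjusted p = 0.637), and without knockout mice 5 and 6 the median was -0.14 and -0.061 (adjusted p = 0.319 and 0.863). The 37 stem cell genes had a median of -0.11, a mean of -0.026 and a test direction of higher (adjusted p = 0.810), and the result turned on the wild type mouse used. The median was 0.20 without mouse 1 (adjusted p = 0.000189) and -0.34 without mouse 3 (adjusted p = 0.00206). Camera adjusted p was 0.308 for G1 cyclins and kinases, 0.324 for signaling receptors and effectors that support stem cells, 0.453 for glycolysis, 0.0518 for the nuclear-encoded respiratory chain, 0.305 for mitochondrially encoded mRNAs, 0.762 for core histones (median -0.096, mean 0.023, test direction lower) and 0.697 for ribosomal proteins. Without wild type mouse 3 the respiratory chain (median 0.085, adjusted p = 0.0178) and the mitochondrially encoded mRNAs (-0.36, adjusted p = 0.00251) passed, while without wild type mouse 1 they had medians of 0.0063 (adjusted p = 0.646) and 0.12 (adjusted p = 0.124), the latter a turn in direction. The respiratory chain also passed under other scalings and filters (0.0400 with total counts only). Non-hematopoietic developmental regulators had 3 measured genes of 57 and the X inactivation and Y-linked list had 2 of 6, too few for the test.

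Camera with the preset correlation called 18 of the 28 lists, 8 higher and 10 lower, and with an estimated correlation it called 0 (4 had an unadjusted p under 0.05). The estimated correlation was 0.766 for erythroid and 0.523 for neutrophil genes. For immediate early and NF-kB genes it was -0.0287 and 0.0107, no more than about the preset 0.01. The loss of those calls therefore does not show that their members move together. The 6 lists that kept their call and direction without any 1 of the 4 libraries were the interferon, immediate early, neutrophil, NF-kB, megakaryocyte, and stroma and endothelium lists.

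The values in 1 row of the authors' deposited table contradict one another. For Hoxb4, a homeobox gene of stem cells (chromosome 11, 96318267 to 96321638), named after its values were seen, the table has 405 and 415 counts in wild type mice 1 and 3, and 499 and 472 in knockout mice 5 and 6. The deposited log2 CPM of 3.13 for knockout mouse 5 corresponds to 401 counts, while 499 counts correspond to 3.44. In every other row the log2 CPM matched the counts to within 2.45e-05. The authors' deposited table gives Hoxb4 a log2 fold change of -0.53, a p of 0.0323 and an adjusted p of 0.958. From the deposited counts the edgeR likelihood ratio test gave a log2 fold change of -0.076. With 401 counts it gave -0.23, from which the deposited value differs by -0.30, and a p that is 10 times the deposited one. This was the only row out of order in a table sorted by p: it stands at row 5265, while 876 rows have a smaller deposited p. By quasi-likelihood Hoxb4 did not pass with either count (adjusted p = 0.865 with 499 and 0.668 with 401).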

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

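The removal of genes high in 1 library and the replacement count for Hoxb4 were chosen after seeing the data. The count of 21 genes was 20 with DESeq2 size factors in edgeR, 20 with total counts only, and 20 without mitochondrial, hemoglobin, X inactivation and Y-linked genes; it was 20 without the genes high in 1 library and 21 with the other Hoxb4 count. The test mattered more: the DESeq2 Wald test called 216 genes (50 at least 2-fold), the likelihood ratio test 177 (78), robust estimation left out 4 (4) and limma voom 0 (0). A filter of 1 CPM in 2 libraries gave 10 genes, from 12772 tested. Leaving out 1 library gave 5 to 855 genes and 5 to 165 at least 2-fold; in these fits the lone library is assumed to vary like the other pair. Of the 21 genes, 20 were called again without either wild type library, 2 without knockout mouse 5 and 6 without knockout mouse 6. In those fits the spread came from the complete pair alone, whose r of log2 CPM was 0.993 for knockout and 0.989 for wild type mice. Calls lost without a knockout library therefore do not show that this library drives the genes. The cause was not tested. Setting no filter removed nothing and tests nothing.

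Pcgf2 was higher in knockout under every setting, from 0.25 to 0.66 in log2 when 1 library was left out, and passed in none. Camera with an estimated correlation called 0 lists, fry 5 (immediate early, interferon, NF-kB, stroma and endothelium, and p53 targets) and camera on ranks 17. With 1 library left out 12 to 18 lists were called, of which 11 to 14 were among the 18 called from all libraries. Over the 68 genes named other than Pcgf2, 7 comparisons with 1 library left out changed direction and 0 under the other alternatives. The genes were not past the threshold before: Bmi1 ranged from -0.056 to 0.18, Mpo from -0.056 to 0.14 and Elane from -0.083 to 0.094, and Iglv3, high in knockout mouse 5 alone, from -0.88 without that mouse to 3.97 without knockout mouse 6. In 32 comparisons with 1 library left out and 51 others a call was lost with its direction kept, and in 57 and 52 a gene not called became called. With the simulated depth and dispersion, 48.8% of 1.5-fold changes were recovered among genes of at least 2 CPM, so changes of that size are often missed.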

Other observations

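The tests of the neutrophil genes were chosen after the result was seen; those of the pseudogenes and of chromosome 11 were not, but the criterion for chromosome 11 was made stricter after its result was seen. A few genes were high in 1 library only, and none of them passed the quasi-likelihood test. Plekhh2 had 378677 counts in knockout mouse 5, or 0.819% of that library, against 71, 113 and 982 counts in wild type mice 1 and 3 and knockout mouse 6. Ppfia4 was at 26.6 CPM in wild type mouse 3 and at 1.45, 1.36 and 1.32 CPM in wild type mouse 1 and knockout mice 5 and 6. The Ig segments Igkv1-88 (89.8 CPM in wild type mouse 1), Iglv3 (107 CPM in knockout mouse 5) and Igkv3-3 (8.15 CPM in knockout mouse 6) were also high in 1 mouse each. Xist exceeded 100 CPM in all 4 libraries, and 0 Y-linked genes of the list were in the table.

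The 4 libraries can be divided into 2 and 2 in 3 ways, too few for a share under 0.05. The real division gave 21 genes by quasi-likelihood and the highest other gave 3. By the likelihood ratio test the values were 177 and 24. The other divisions put a wild type and a knockout mouse in each group. A real difference between the genotypes would widen the spread there and lower those counts, so they are no baseline for the 21 genes.

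Lower neutrophil transcripts lay among members of the list not classed as early. The median log2 fold change was -0.67 over these 29 members, called late, and -0.0098 ± 0.082 (SD) over 7 early members. Fewer neutrophil lineage cells of every stage would lower the early genes too, and they were not lower as a group. This does not decide against it, since the early genes were set apart after the result was seen. A wild type library with more neutrophil RNA than the rest stays open: the late median kept its direction at -0.44 without mouse 3 and -0.76 without mouse 1, but each value rests on 1 wild type library. Only the knockout pair then gives a spread between mice, and the spread between wild type mice is unknown in these fits. Fewer late stage neutrophils among the sequenced cells may also account for the pattern, and the count of late genes lower in both knockout libraries, 26 of 29, does not decide it, since these genes were set apart after the result was seen and move together; the most abundant, S100a9, went from 6450 to 3792 CPM without passing the quasi-likelihood test. Lower expression per cell in the knockout would give the same values, so these cannot be told apart. A lineage-negative sort should remove mature neutrophils from both groups, but the purity of the sort was not examined. The neutrophil transcript Retnlg was at 554 CPM in wild type and 294 CPM in knockout.

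Reads of the processed pseudogenes Gm5823 (chromosome 18, 79959006 to 79959539) and Gm18860 (chromosome 8, 71704205 to 71704968) were 205 times (95% exact interval 87.7 to 633) and 61.2 times (29.5 to 153) as frequent in knockout as in wild type libraries. These intervals cover counting error only, not the spread between mice. In knockout mice 5 and 6, Gm5823 was at 18.4 and 9.70 CPM and Gm18860 at 7.34 and 4.39 CPM. The genes closest to the 2 pseudogenes by sequence were Arf1 (94.9% identity over 549 bp) and Cnot8 (97.8% over 760 bp). A constant rate of misassigned parent reads would need those genes to rise likewise, and their log2 fold changes were -0.14 ± 0.094 and -0.25 ± 0.080 (SE). A variant parent allele whose reads map to the pseudogene could move reads from one to the other: Arf1 was lower by 25.7 CPM where Gm5823 gained 13.96, and Cnot8 by 13.1 CPM where Gm18860 gained 5.77, neither past the quasi-likelihood test (adjusted p = 0.675 and 0.439). Such an allele, transcription of the pseudogenes themselves and an effect of the genotype cannot be told apart without reads.

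DNA of another strain carried along beside the targeted Pcgf2 locus might change genes near it. Of the 177 genes called by the likelihood ratio test, 2 (Gh and Itgb3) lay within 10 Mb of Pcgf2, or 1.13%, against 1.86% of the other genes (one-sided Fisher's exact p = 0.843; odds ratio 0.603, upper 95% bound of the share 4.02%). The other 175 lay elsewhere, which argues against effects of linked DNA on genes in that window as the source of the change in general. A linked variant that acts on genes elsewhere was not tested by gene position. It stays open, as do those 2 genes and unlinked strain differences.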
